A study of Rattus norvegicus with 6 samples.

How the data were processed

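Total RNA from whole hippocampus of SHA and SLA rats was measured, per the labels, in 6 pools of 3 rats, 3 pools per line, on 6 one-colour oligonucleotide arrays of a rat design. The authors deposited 1 linear intensity per probe set and array. The values have 1 decimal and none is below 0. Their 2%-trimmed mean over all probe sets lay between 250.3 and 250.4 on the 6 arrays, so each array had already been scaled to a common mean, and the deposited intensities were used as they stand. The software, its version and the scaling target are not given in the sources used here. Detection calls and scanner values were not used here. Equal trimmed means fix the overall level of each array, so a shift shared by all transcripts would not be seen.

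Of 8799 probe sets, 59 are array controls and entered only the checks of array quality. Values below a floor of 8.9, the 10th percentile of the remaining values, were set to that floor and log2 was taken. Between 4.95% and 15.9% of an array's values lay at the floor. The 25% of probe sets with the lowest mean log2 value was left out, which left 6555. Differences of probe sets at the floor in some pools depend on that floor. Gene names came from the platform annotation, with symbols updated through gene numbers in a reference gene table of assembly GRCr8, where 6985 probe sets with 1 symbol matched. Of 8740 probe sets other than controls, 7006 had 1 gene symbol, 308 had several and 1426 had none listed, and only those with 1 symbol are named. Where several probe sets name 1 gene, the list tests took the brightest, which gave 3812 genes.

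Lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 25 lists, with camera with an estimated correlation and fry beside it. No list passed with an estimated correlation. The self-contained test fry, which asks whether the genes of a list move one way on balance, gave adjusted p values of 0.64 for antigen presentation, 0.33 for the immune markers and 0.97 for oxidative phosphorylation. The lists hold 957 distinct entries, of which 686 distinct genes were measured. Named genes followed a rule: in each direction the 10 genes of smallest p among probe sets whose pools did not overlap, since fewer than 10 passed, then up to 4 genes per list in its main direction and 2 in the other where the unadjusted p was under 0.05, and genes with at least 2 probe sets at an unadjusted p under 0.01. The rule, the lists, the tests and most alternative settings were fixed before the data were examined. Cd74, the Lin7 genes and Ykt6 were put in the lists with some memory of earlier work on these rat lines, so they are not independent of it, and the lists were also tested without them. The prefix rule for ribosomal proteins also took Rps6kb1 and Rpl3l, which are not ribosomal proteins of that group.

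Pools of both lines carry the numbers 1 to 3, and no label says what a number shares. Deviations from the line means correlated between same-numbered pools at 0.44, 0.68 and 0.13 for numbers 1, 2 and 3, so the numbers were taken to pair the pools and blocked values are given where they change a call or move a count. The pairing comes from the data alone, and SHA pool 3 correlated slightly more with SLA pool 1, at 0.16. Arrays correlated with one another at Pearson r between 0.779 and 0.963 across probe sets, so no array duplicated another. The highest value was between lines, for SHA pool 2 and SLA pool 2, while SLA pools 1 and 2 correlated at 0.787. Pools of a line were thus not always more alike than pools of different lines.

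The alternatives were quantile normalization, median centring, other filters and floors, no or a robust intensity trend, array weights, the pool number as a block, leaving out each pool in turn, other thresholds, the mean of a gene's probe sets and an estimated correlation. Leaving out both pools numbered 1, combining block and weights, and the lists without the recalled genes were added after the data were seen. Pipelines were first tested on simulated data. For this comparison with 6555 probe sets, 200 of them changed and no pairing, 3.7% of 2-fold, 37.4% of 4-fold and 58.1% of 8-fold changes were recovered on average over 20 draws, with 1.8 false calls among 51.6. With simulated pairing of the same-numbered pools, 0% of 2-fold, 9.1% of 4-fold and 28.6% of 8-fold changes were recovered. With the block, 3.5% of 4-fold and 21.9% of 8-fold changes were recovered in these paired draws. The paired draws added a shared deviation on top of the full noise, so the lower recovery cannot be put down to pairing alone. With 3812 genes, the oxidative phosphorylation list shifted by 0.3 was called in 19 of 20 draws. That shift is larger than the median difference of 0.11 seen for this list in the data, so power at that size was not tested. Over these draws and 20 more without a shift, 3 calls fell on lists that had not been shifted. Noise was drawn independently for each gene, so these draws do not show how camera behaves where genes of a list vary together.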

Results

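Gene expression in the whole hippocampus was compared between 2 rat lines, the Syracuse High Avoidance (SHA) and the Syracuse Low Avoidance (SLA) rats. The lines are named for how well the animals learn two-way active avoidance. In this task a rat can avoid a signalled shock by crossing to the other side of a box. Tissue had been taken 2 weeks after that testing in all pools. No untested rats were measured, so differences that the lines had before testing cannot be told apart from effects of the testing. Each line was represented by 3 pools of 3 rats, and each pool was measured on its own oligonucleotide array with 8799 probe sets. As far as the labels state, the pools hold different rats, so the pool is the replicate and n = 3 per line throughout. Intensities are linear values on the authors' scale, given as mean ± SD over pools, and differences are log2 SHA minus SLA ± standard error. The 2%-trimmed mean intensity was 250 on the 6 arrays, and the number of arrays limits the precision.

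The comparison asked which hippocampal transcripts differ between rats of the high and the low avoidance line. Cd74, the invariant chain that accompanies MHC class II molecules, had the smallest p of the 6555 probe sets tested and was lower in SHA. Its probe set X13044_at read 8.47 ± 1.70 in SHA and 154 ± 82.8 in SLA, with 2 of the 3 SHA pools at or under the floor of 8.9. The second probe set, X13044_g_at, had no pool at the floor and read 15.6 ± 6.77 against 124 ± 116, a difference of -2.67 ± 0.76. Among genes higher in SHA, Psmb4, a proteasome subunit, had the smallest p on probe set rc_AI172162_at, at 2194 ± 720 against 766.5 ± 73.6, a difference of 1.47 ± 0.27. The other 2 probe sets of Psmb4 differed by -0.12 and 0.11, so it is uncertain that this one reads Psmb4. No probe set passed limma's test at an adjusted p under 0.05. The lowest adjusted p was 0.81 for Cd74, and the genes named below have an adjusted p of 1.00 unless another value is given.

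At an unadjusted p under 0.05 there were 98 probe sets, 24 higher and 74 lower in SHA, where 328 would arise by chance among independent pools. The same count was 109 after quantile normalization (36 higher, 73 lower) and 92 after median centring (32 higher, 60 lower). The 3 SHA pools lay wholly above or wholly below the 3 SLA pools for 371 probe sets, 132 higher and 239 lower, or 5.66% against the 10% that chance gives for 6 exchangeable pools. Pools paired by number are not exchangeable, so neither chance value holds exactly here. That split was 188 to 206 after quantile normalization and 149 to 173 after median centring. With the pool number as a block, 345 probe sets had an unadjusted p under 0.05 (149 higher, 196 lower), and none passed. The lowest adjusted p was then 0.13, for Psmb4. The unblocked count was 61 without SHA pool 1, 149 without SHA pool 2, 154 without SLA pool 2 and 58 without SLA pool 3. With the block and array weights together, a setting chosen after the data were seen, 12 probe sets passed, 5 higher and 7 lower, among them those of Cd74, Ctrc, Myh1, Nnat, Psmb4, RT1-A, RT1-CE16, Vegfa and Vps52.

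The 10 genes with the smallest p among those higher in every SHA pool than in any SLA pool were Psmb4 and the following, none past the threshold. Vdac1, the outer-membrane channel of mitochondria, read 601 ± 106 in SHA and 285 ± 85.5 in SLA (1.11 ± 0.30), and its other probe set also lay higher. Got2, the mitochondrial aspartate aminotransferase, differed by 1.34 ± 0.47, with 2.60, 0.55 and 0.88 within the numbers 1, 2 and 3 and 0.71 without the pools numbered 1. Syngr1, a synaptic vesicle membrane protein, read 131 ± 19.9 against 34.8 ± 9.12 (1.93 ± 0.46). Nnat, an imprinted gene of the developing and adult brain, read 2511 ± 219 against 1349 ± 314 (0.92 ± 0.24). Vegfa, an angiogenic growth factor, read 199 ± 27.9 against 69.0 ± 33.5 (1.62 ± 0.43). Dusp6, a phosphatase of ERK, differed by 1.08 ± 0.38. Myh1, a myosin heavy chain, read 689 ± 41.7 against 360.2 ± 69.7 (0.95 ± 0.24). Slc3a1, a subunit of an amino acid transporter, differed by 1.21 ± 0.33, and Tnfrsf11b, osteoprotegerin, by 2.03 ± 0.69. The Tnfrsf11b difference was 1.90, 0.52 and 3.66 within the numbers, 1.39 without SLA pool 3, 2.67 without SLA pool 2 and 1.17 with block and array weights. Differences between pools sharing the numbers 1, 2 and 3 were 1.85, 1.32 and 1.25 for Psmb4, 1.41, 0.67 and 1.25 for Vdac1 and 1.60, 1.77 and 2.42 for Syngr1. Probe sets of a gene did not always go together: besides Psmb4, the other 2 of Syngr1 differed by -0.62 and 0.22 and the other 3 of Vegfa by -0.17, 0.17 and 0.21.

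The 10 genes with the smallest p among those lower in SHA included 4 of antigen presentation, again with none past the threshold. Besides Cd74 these were RT1-Da, an MHC class II chain, at 40.5 ± 12.2 against 195 ± 88.5 (-2.22 ± 0.49), and the class I genes RT1-A, at 468 ± 23.8 against 819 ± 68.8 (-0.81 ± 0.22), and RT1-CE16, at 697 ± 156 against 1207 ± 135 (-0.81 ± 0.25). The class I probe sets are designed to a gene family and can read related RT1 transcripts, so their gene is uncertain. Vps52, a subunit of a complex for retrograde vesicle transport, read 262 ± 62.1 in SHA and 623 ± 118 in SLA (-1.26 ± 0.29). Serping1, the C1 inhibitor of the complement system, read 34.3 ± 5.24 against 150 ± 80.5 (-2.01 ± 0.51). Tgfbr1, a receptor of TGF-beta, read 13.8 ± 0.26 against 60.8 ± 13.2 (-2.12 ± 0.62), close to the floor in SHA, and differed by -1.21 with the floor at the 25th percentile. Vim, the intermediate filament vimentin, differed by -1.10 ± 0.35, Apoa2, an apolipoprotein, by -2.53 ± 0.68 with 1 SHA pool at the floor (-1.59 with the floor at the 25th percentile), and Kcne1, a potassium channel subunit, by -1.43 ± 0.49. Differences between pools sharing the numbers 1, 2 and 3 were -3.46, -2.44 and -2.12 for Cd74 on X13044_g_at, -3.48, -1.73 and -1.47 for RT1-Da and -1.26, -1.16 and -1.37 for Vps52.

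**Figure D1:**
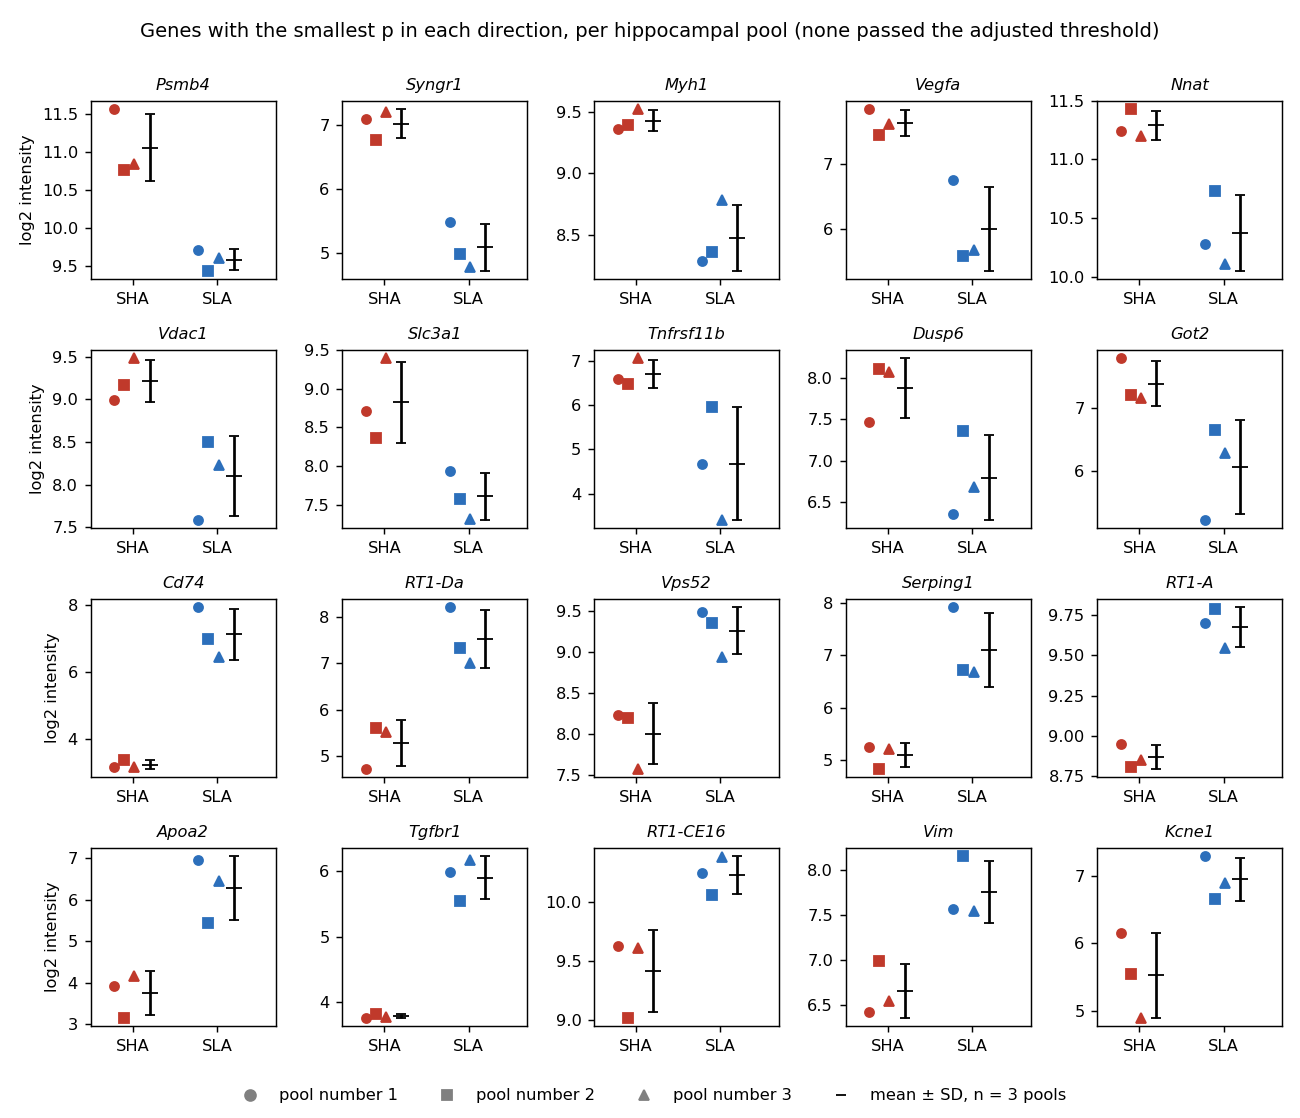
Log2 intensity of the 10 named genes higher and the 10 lower in SHA, 1 point per hippocampal pool with the symbol giving the pool number, and the mean ± SD of the 3 pools of each line beside the points. The 3 pools of one line lie wholly above those of the other in each panel by the rule that chose the genes, and none passed the adjusted threshold.

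Of 25 gene lists fixed before the data were examined, 3 passed limma's camera test, which compares the genes of a list with the other genes measured. Antigen-presentation genes fell as a group in SHA relative to the other genes: 16 of the 19 measured were lower and 3 higher, with a median difference of -0.38 (adjusted p = 2.2e-06, and adjusted p = 0.37 with an estimated correlation). RT1-CE12, a class I gene, differed by -0.63 ± 0.22, and RT1-Ba, a class II chain, by -1.26 ± 0.47, with 117 ± 63.4 in SHA and 251 ± 45.5 in SLA. The other 2 probe sets of RT1-Ba differed by -0.70 and 0.08, and the difference was -0.75 without SHA pool 1. Microglia and immune markers also fell as a group, with 22 of 25 lower and 3 higher and a median of -0.41 (adjusted p = 1.3e-05, and adjusted p = 0.23 with an estimated correlation). C3, the central complement component, read 30.6 ± 15.7 against 80.4 ± 13.0 (-1.51 ± 0.58), and C1qb, a chain of complement C1q, 315 ± 57.6 against 479 ± 63.4 (-0.61 ± 0.26). The 2 lists share 7 measured genes. Medians within the pool numbers 1, 2 and 3 were -0.62, -0.46 and -0.01 for antigen presentation and -0.77, -0.38 and -0.23 for the immune markers. No gene of either list passed over all probe sets, and none did when adjusted over the list alone. Cd74 entered the lists with X13044_g_at, its brighter probe set on the log2 scale. X13044_at, which had the smaller p, did not enter, so the call for Cd74 can depend on that choice. With the pool number as a block, Cd74, RT1-CE12 and RT1-CE16 passed when adjusted over the list alone. Cd74 and RT1-Da did so without SHA pool 1 and without SHA pool 3. Without either of these pools Cd74 was read from X13044_at and RT1-Da from M15562_g_at, the probe set whose values are given above. With all pools the list read RT1-Da from its other probe set, which had no unadjusted p under 0.05. For both genes, then, the pools and the probe set changed.

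Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, rose as a group in SHA relative to the other genes. Of 54 measured, 43 were higher and 11 lower, with a median difference of 0.11 (adjusted p = 5.3e-04, and adjusted p = 0.66 with an estimated correlation). Subunits of complex I, chosen as examples after their values were seen, differed by 0.44 ± 0.22 (Ndufa5), 0.49 ± 0.25 (Ndufa6) and 0.59 ± 0.33 (Ndufb9), none past the threshold. No member passed over all probe sets or adjusted over the list alone. Medians within the pool numbers 1, 2 and 3 were 0.19, 0.18 and -0.04. Without SHA pool 1 the list's adjusted p was 0.50, and without SLA pool 2 it was 0.11.

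**Figure D2:**
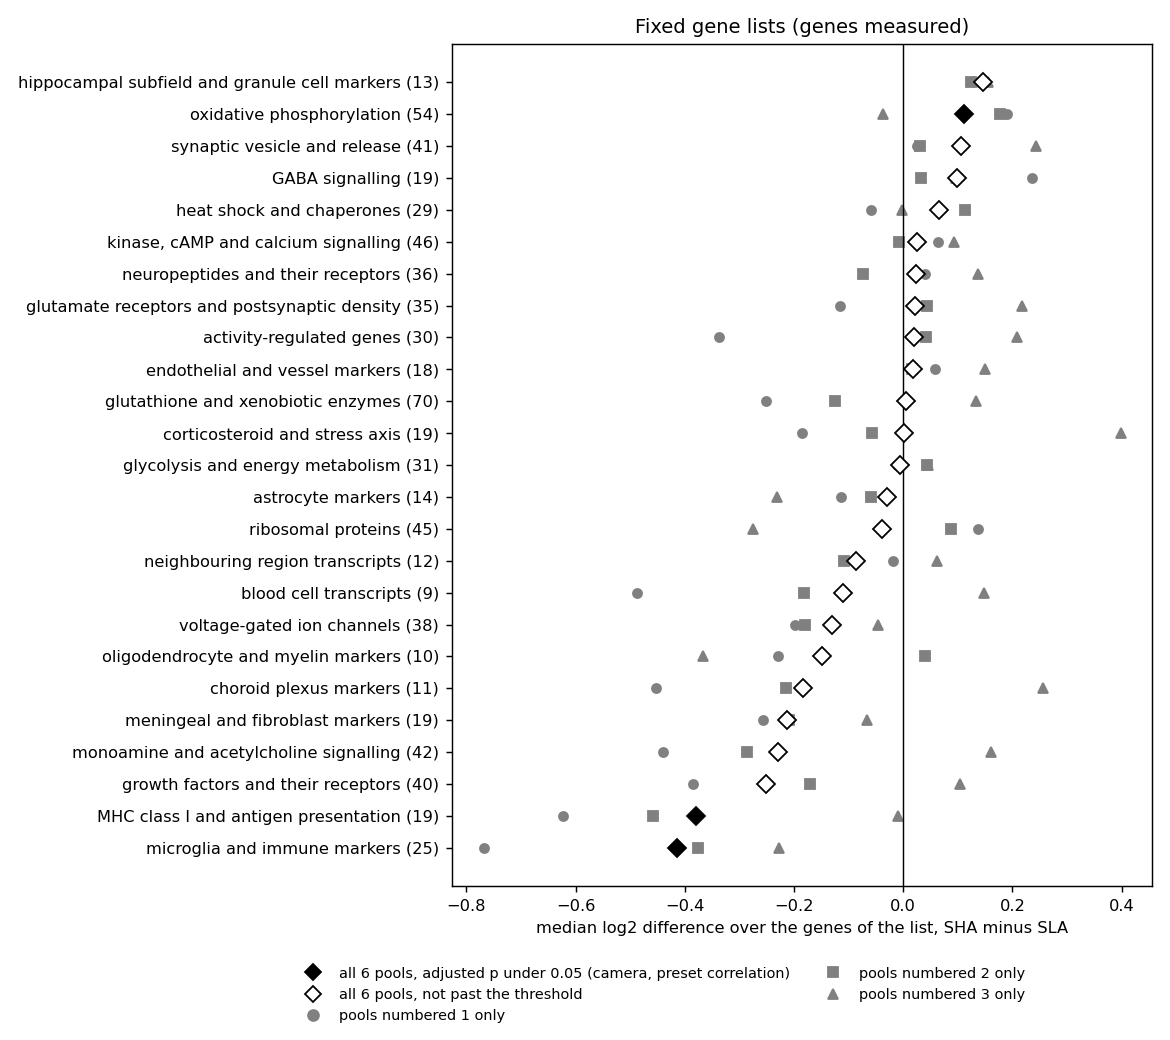
Median log2 difference, SHA minus SLA, over the measured genes of each of the 25 lists, with the number of genes in brackets; diamonds are the medians over all 6 pools, filled where camera with a preset correlation passed, and grey symbols are the medians within each pool number. The filled diamonds lie at -0.41 (microglia and immune), -0.38 (antigen presentation) and 0.11 (oxidative phosphorylation).

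In the main setting no list of synaptic or transmitter genes passed. Further members named from here on, other than Slc6a4, Dusp6, Tgfbr1, Vim and Hmox1, were chosen as examples after their values were seen, and no member of these lists passed over all probe sets or adjusted over the list alone. With the block, Vim passed when adjusted over the list alone. Of 41 synaptic vesicle and release genes, 28 were higher and 13 lower (median 0.11, adjusted p = 0.096), among them Rph3a (1.10 ± 0.54) and Rab3a (0.43 ± 0.26). This list's adjusted p was 0.039 with the pool number as a block, 0.040 with array weights, 0.030 with the mean of a gene's probe sets, 6.5e-04 without SHA pool 1 and 0.0018 without SLA pool 2. With an estimated correlation its adjusted p was 0.51 in the blocked fit and 0.66 in the unblocked fit, and its medians within the numbers were 0.03, 0.03 and 0.24. Glutamate receptor and postsynaptic genes had 20 of 35 higher (median 0.02, adjusted p = 0.38), with Gria2, an AMPA receptor subunit, at 0.54 ± 0.27. GABA signalling genes had 11 of 19 higher (median 0.10, adjusted p = 0.26), with the receptor subunits Gabra4 at 1.16 ± 0.60 and Gabbr1 at -0.46 ± 0.23. This adjusted p was 0.020 without SHA pool 1 and 0.014 without SLA pool 2. Monoamine and acetylcholine genes had 29 of 42 lower (median -0.23, adjusted p = 0.10). Slc6a4, the serotonin transporter, read 135 ± 22.6 against 238 ± 30.8 (-0.82 ± 0.31), and both of its probe sets lay lower. Medians of that list within the numbers were -0.44, -0.29 and 0.16, and its adjusted p was 0.031 without SHA pool 3, 0.032 without SLA pool 2 and 0.027 without SLA pool 3.

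Neuropeptides and their receptors had 19 of 36 higher (median 0.02, adjusted p = 0.11), among them Cck at 0.41 ± 0.22 and Sstr5 at 1.35 ± 0.61, and the adjusted p was 0.020 without SHA pool 2. Voltage-gated ion channels had 22 of 38 lower (median -0.13, adjusted p = 0.25), and the adjusted p was 0.026 without SHA pool 2 and 0.0054 without SLA pool 1. Kinase, cAMP and calcium signalling genes had 26 of 46 higher (median 0.02, adjusted p = 0.26). Growth factors and their receptors had 27 of 40 lower (median -0.25, adjusted p = 0.26), Tgfbr1 among them. Corticosteroid and stress-axis genes had 10 of 19 higher (median 0.00, adjusted p = 0.40). Nr3c1, the glucocorticoid receptor, differed by -0.66 ± 0.85, and Hsd11b1, which regenerates active glucocorticoid, by 0.53 ± 0.26. Activity-regulated genes, in tissue taken 2 weeks after testing, were split 15 to 15 (median 0.02, adjusted p = 0.43), with Arc at -0.36 ± 0.32, Fos at -0.33 ± 0.27 and Dusp6 on the higher side. Hippocampal subfield and granule cell markers had 8 of 13 higher (median 0.15, adjusted p = 0.11), with Calb1 at 0.73 ± 0.41.

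Markers of other cell types showed no list past the threshold apart from the immune markers. Astrocyte markers had 6 of 14 higher (median -0.03, adjusted p = 0.88), with Vim lower and the glutamate transporter Slc1a3 at 0.45 ± 0.26. Oligodendrocyte and myelin markers had 8 of 10 lower (median -0.15, adjusted p = 0.28), with Mbp at -0.11 ± 0.38. Choroid plexus markers had 9 of 11 lower (median -0.18, adjusted p = 0.40), although Ttr, an abundant transcript of that tissue, differed by 0.21 ± 0.44. Endothelial markers were split 9 to 9 (median 0.02, adjusted p = 0.47). Meningeal and fibroblast markers had 13 of 19 lower (median -0.21, adjusted p = 0.25), and the adjusted p was 0.034 without SHA pool 1. Blood cell transcripts had 6 of 9 lower (median -0.11, adjusted p = 0.82), and transcripts of neighbouring brain regions 7 of 12 (median -0.09, adjusted p = 0.82).

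Among housekeeping groups, ribosomal protein genes had 26 of 45 lower (median -0.04, adjusted p = 0.96), and without SHA pool 1 the adjusted p was 0.0065, with the list lower. Glycolysis genes had 16 of 31 lower (median -0.01, adjusted p = 0.25). Heat shock and chaperone genes had 17 of 29 higher (median 0.07, adjusted p = 0.29), while Hmox1, the inducible haem oxygenase, read 56.4 ± 33.8 against 135 ± 19.9 (-1.41 ± 0.50), with -1.86, -0.41 and -1.97 within the numbers and -0.82 with block and array weights. Glutathione and xenobiotic enzymes had 36 of 70 higher (median 0.00, adjusted p = 0.79). For the blood cell, neighbouring region, ribosomal and glycolysis lists the median was below 0 while camera placed the list above the other genes, and the glutathione list had a mean of -0.02 with camera's direction up.

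The arrays differed by pool number in their control probe sets. Geometric mean intensities of the added bacterial and phage controls were 5458 and 12282 in the SHA and SLA pools numbered 1, 1121 and 640 in those numbered 2, and 2279 and 1564 in those numbered 3. Probe sets for the antisense strands of Gapdh and beta-actin read 1352 and 1432, 30.1 and 21.3, and 365 and 219 in the same order. The 3' to 5' difference of Gapdh, a sign of RNA integrity, was 0.20 ± 0.13 in SHA and 0.17 ± 0.23 in SLA, and that of beta-actin was 0.66 ± 0.11 and 0.52 ± 0.10. Neither separated the lines in a two-sided exact permutation test (p = 0.9 and p = 0.2, adjusted p = 1 over 8 measures), where 3 pools against 3 allow no p under 0.1.

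**Figure D3:**
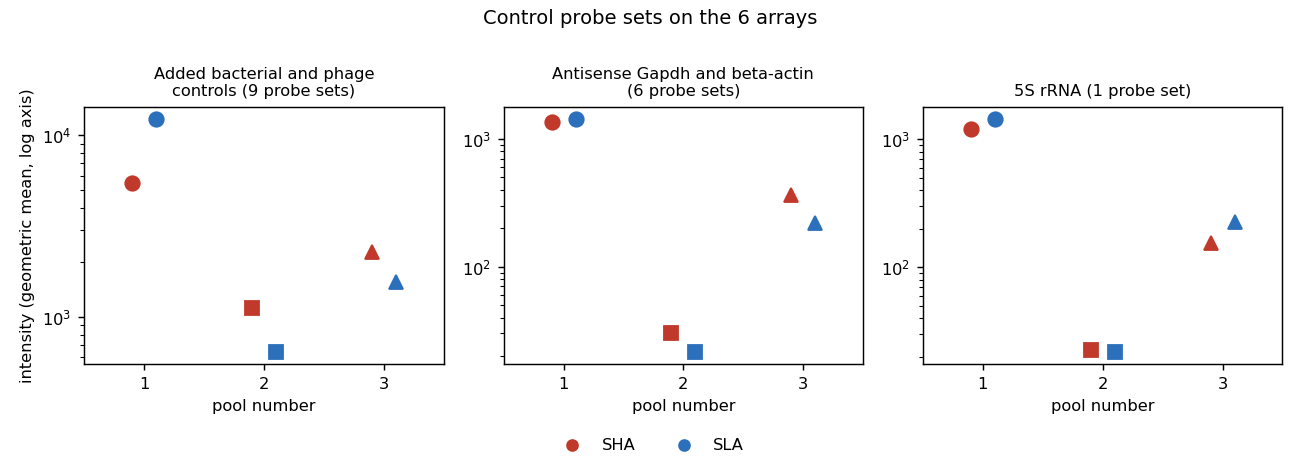
Intensity of 3 groups of control probe sets on a log axis against pool number, 1 point per array, red for SHA and blue for SLA (geometric means over 9 added controls and 6 antisense probe sets, and the single 5S rRNA probe set). For the antisense probe sets and 5S rRNA the arrays of a number lie closer together than arrays of different numbers, with 5S rRNA at 1205 and 1439 for number 1 and 22.5 and 21.6 for number 2.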

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

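The setting that leaves out both pools numbered 1, the block with array weights and the lists without recalled genes were chosen after the data were seen. Under 18 settings the 27 named probe sets gave 476 values, and the stricter filter removed 10 more. Of the 476, 468 kept their side of the threshold and 8 passed (all with block and array weights). None reversed, but most settings could not reverse probe sets whose pools did not overlap. The count of 0 probe sets past the threshold held in limma under the settings run except the block with array weights, with 12, and the looser limit of an unadjusted p under 0.01, with 19. At an unadjusted p under 0.05 the count of 98 became 203 with no filter, 63 with the dimmer 50% left out, 354 with array weights, 345 with the replicate block, 871 with block and weights, and 58 to 154 when 1 pool was left out (61 without SHA pool 1, 149 without SHA pool 2, 154 without SLA pool 2, 58 without SLA pool 3). With block and weights 1 gene of the fixed lists passed over all probe sets and 18 adjusted over the list alone. Adjusted over the list alone, 1 passed after quantile normalization (Cd74) and 1 with the floor at the 25th percentile (Cd74). With no intensity trend 1 passed (Tgfbr1), and with array weights 1 (RT1-CE16). With the replicate block 4 passed (Cd74, RT1-CE12, RT1-CE16, Vim), and 0 to 2 did when 1 pool was left out. After quantile normalization, with the floor at the 25th percentile and without SHA pool 1 or 3, Cd74 was read from X13044_at, not X13044_g_at. Those Cd74 calls thus changed both the setting and the probe set. RT1-Da, which passed without SHA pool 1 or 3, was likewise read there from a probe set the list did not use with all pools. The count of 3 lists became 0 with an estimated correlation, 5 without the pools numbered 1, 7 with the mean of a gene's probe sets and 4 to 6 when 1 pool was left out (6 without SHA pool 1, 5 without SHA pool 2 and 5 without SLA pool 2). With an estimated correlation the adjusted p was 0.37 for antigen presentation, 0.23 for the immune markers and 0.66 for oxidative phosphorylation. Leaving out 1 pool gave 6.0e-08 to 0.50 for oxidative phosphorylation (0.50 without SHA pool 1, 0.11 without SLA pool 2) and 6.5e-04 to 0.84 for the synaptic vesicle list (6.5e-04 without SHA pool 1, 0.0018 without SLA pool 2). The vesicle list had 0.040 with array weights, 0.039 with the replicate block, 0.034 without the pools numbered 1 and 0.030 with the mean of probe sets. Other lists also passed: kinase signalling (0.040), hippocampal subfield markers (0.0090) and glycolysis (0.030) with the mean of a gene's probe sets, activity-regulated genes (0.034) without the pools numbered 1, and heat shock genes (0.020) with block and weights. The block changed no other list's call. Without Cd74, the Lin7 genes and Ykt6, antigen presentation had 4.4e-05 and the immune markers 1.5e-04. Apart from the settings' own construction (fewer pools, fewer probe sets, a stricter or looser limit), the cause was not tested. The robust trend was not run for the lists, since camera has no such option. Signal over background limited dim genes, and Cd74 on X13044_at ranged from -4.24 to -2.44 over the settings, X13044_g_at from -3.07 to -1.87. With the floor at the 25th percentile Tgfbr1 differed by -1.21 and Apoa2 by -1.59. Without the pools numbered 1, Got2 differed by 0.71 and RT1-Ba by -0.60.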

Other observations

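Tests on Cd74 and on the neighbours of Vps52 were chosen after the results were seen, as were the probe sets of the next sentences. Probe sets from a single sequence record, unnamed here, were lower in SHA: AF028784cds#1_s_at at 989 ± 192 against 2236 ± 800 (-1.14 ± 0.30), AF028784mRNA#1_s_at at 4077 ± 513 against 8134 ± 2732 (-0.95 ± 0.31) and AF028784mRNA#2_at at 59.2 ± 19.7 against 269 ± 153 (-2.10 ± 0.48). None passed the adjusted threshold. With no gene listed for them they entered no gene list, so no list result above, that of the cell type markers included, takes them into account. Within the pool numbers 1, 2 and 3 the brightest of them differed by -1.41, -0.35 and -1.09.

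The antigen-presentation list was lower in SHA. The arrays numbered 1 as the whole cause were argued against, since without them the median was -0.28 beside -0.38 with all pools. Medians within the numbers 2 and 3 were -0.46 and -0.01, so effects of other arrays were not tested by this. Fewer microglia or other immune cells in the SHA pools may account for the list, since the 18 immune genes outside antigen presentation had a median of -0.40. Its 95% bootstrap interval, -0.58 to -0.21, is over genes that share the same pools, so it leaves out the spread between pools. A mismatch of RT1 probe sets to the alleles of one line stays open: 81.8% of these probe sets (18 of 22) were lower in SHA, but they share the same pools and can read related transcripts, so they are not independent. Cd74, whose probe set X13044_at had the smallest p, differed by -2.67 on X13044_g_at (95% interval -4.37 to -0.98). This value decides between neither explanation, because the gene was picked for its difference. A regulatory difference between the lines stays open untested. The smallest camera p for the list was that of the real split, 1 of 10 (8.9e-08 against 3.5e-04 for the next). The list was also called by 2 of the 9 other splits, and 10 splits are too few for a share under 0.05. The 3 other splits that part all same-numbered pairs gave a camera p of 3.5e-04, 0.046 and 0.78.

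The oxidative phosphorylation list was higher in SHA. A dependence on signal brightness was tested with 10000 lists matched on mean signal. Their medians lay between -0.05 and 0.08 (central 95%), and the list's 0.11 lay at percentile 99.7. The matched lists hold unrelated genes, while genes of this list may vary together, so the percentile may be too high and brightness stays open. The arrays numbered 1 as the whole cause were argued against, since the median was 0.084 without both beside 0.11 with all pools. Without SHA pool 1 alone, however, camera's adjusted p was 0.50. Medians within the numbers 2 and 3 were 0.18 and -0.04, so effects of other arrays were not tested by this. A larger share of neuronal RNA cannot be told apart, since 95 neuronal genes had a median of 0.10 and glial genes one of -0.07. The interval of the neuronal median, 0.02 to 0.15, is likewise over genes that share the same pools. A difference in mitochondrial expression between the lines stays untested. Of the 10 splits, 3 gave as small a camera p (real 6.4e-05, smallest other 7.6e-12). The list was called by 5 of the 9 other splits, and 10 splits are too few for a share under 0.05. The 3 other splits that part all same-numbered pairs gave a camera p of 1.0e-05, 0.90 and 0.69.

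Vps52 lies near the RT1 genes in the reference gene order. A stretch of neighbouring genes that differs between the lines could include it, but the 33 other measured genes of that block had a mean absolute t at percentile 62.3 of 3084 stretches of as many neighbours, which leaves this open.

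Over the 10 splits, 7 gave at least the 98 probe sets of the real split at an unadjusted p under 0.05, with a highest other of 1229, and 8 gave at least its 3 lists, with a highest other of 10. These splits are too few for a share under 0.05. The split with 1229, SHA pools 1 and 3 with SLA pool 1 against the rest, points to a structure of the samples beyond line. Among the 4 splits that part all 3 same-numbered pairs, the blocked count was 345 for the real one and 128, 245 and 349 for the others. The unblocked count of lists was 3 for the real one and 0 to 4 for the others.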
